A study of Mus musculus with 2 samples.

How the data were processed

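The data are lists of regions called from ChIP-seq of corneal epithelium from K14 DN-Clim mice with an antibody against the Myc tag of the transgene product, with 2 replicates in 1 group. Per the labels' protocols, the epithelium was released with dispase for 2 hours at 37 °C and then fixed, each immunoprecipitation used 24 µg of sonicated chromatin, and the libraries were amplified before size selection. Per the labels' protocols, both libraries were multiplexed in the same lanes, 2 lanes of 50-cycle single-end reads were sequenced, and the reads of the lanes were combined after alignment. Each list therefore belongs to 1 replicate, and no list of pooled replicates was used here. Amplification and the stacking of reads at one base can both raise the count of reads in a short region.

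Bowtie 0.12.7, bedtools 2.11.2 and the mm9 genome build are named in the submitters' processing notes, without their settings. The names of the regions carry the prefix of the peak caller MACS. Its version, its thresholds and any control library are not given in the sources used here. The lists give chromosome, start, end, name and a score for each region, without a header. The score is the peak caller's own value as deposited by the authors, and what it measures is not stated. Its form may be that of a transformed p-value, which would make it depend on the depth of each library and on limits that differ between the lists, but this was not tested. For that reason it was used mainly to rank or filter regions within a list. The exceptions are the correlation of scores over shared pairs and the limit of sample 2 at the lowest sample 1 score, which assumes that a score means the same in both lists. The lowest deposited score differed between the lists, so the authors' limits for keeping a region may have differed. Neither read counts nor library totals are part of the lists, so depth and the precision it gives could not be computed, and no count test was run.

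Regions were sorted and compared with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 in Python 3.11.15. A region was shared when it overlapped a region of the other list by at least 1 bp. Overlapping regions of both lists were merged, and the strength of a merged region was the mean of its score percentiles in the lists. The chance level came from 100 random placements of the sample 2 regions, with chromosome and length kept, within the span from the first to the last region of either list on each chromosome. Assembly gaps were not avoided, because no sequence of this build was used here. Shares carry exact (Clopper-Pearson) 95% intervals. The expected share of a chromosome was its part of the spanned length over chromosomes 1 to 19 and X. Protein-coding genes per chromosome were counted in a RefSeq table of the GRCm38 assembly, from which no coordinates were taken. The correlation with gene density used 100000 permutations and Benjamini-Hochberg adjustment. Intervals of Spearman's rho used Fisher's transformation over pairs. The boundary between narrow and wide regions was the emptiest 5-bp bin of each list's width histogram between the narrow and the wide population, and was set after the widths were seen. Coordinates are printed counting from 1.

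The overlap code was tested on simulated data: 12000 of the 25592 sample 1 regions were planted in a random second list, and all 12000 were found, with 31 overlaps by chance in addition. For the real lists, bedtools 2.31.1 gave the same count of 20582.

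The tests of overlap, score agreement and chromosome distribution, a first set of alternatives and the rule for named items were fixed before the data were examined. The comparison of edges, the gene density relation, the width classes, the limit of sample 2 to the lowest sample 1 score, its reduction to the length of sample 1 and the shift by a fixed distance were added after the data were seen, as were the values near chromosome starts and the distances to the nearest shared region. The rule for named items named the 10 strongest shared regions and the 5 windows of 100 kb with most shared regions, if no annotation on the build of the lists was at hand. Other regions in the text were chosen after their values were seen. The location of regions relative to genes, genes with a region at their promoter, the enrichment of gene lists and the enrichment of sequence motifs had also been planned. They were left out, because they need an annotation or a sequence in mm9, and coordinates were not converted between builds. The alternatives run were another overlap rule, a stricter score limit, each list on its own, and another expectation per chromosome.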

Results

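Chromatin immunoprecipitation followed by sequencing was carried out on corneal epithelium from mice at postnatal day 7. The mice carried the K14 DN-Clim transgene, which places a Myc-tagged dominant-negative form of Clim under the keratin 14 promoter, a promoter active in basal epithelial cells. Clim proteins, also named Ldb or Nli, are nuclear cofactors that bind LIM-domain transcription factors and have no DNA-binding domain of their own. The antibody was directed against the Myc tag of the transgene product. Whether a called region reflects recovery of the tagged protein was not tested. The title of the series places the work in the maintenance of limbal stem cells, the progenitors at the rim of the cornea. The data comprised 1 group of 2 replicate immunoprecipitates, each with its own list of called regions in mm9 coordinates. No wild-type, input or untagged library was analysed here, so no background value can be set beside the counts. Read totals are not given in the sources used here, so the depth behind each region is unknown. The intervals below cover counting error over regions only, and they treat regions as independent. Nothing in the labels says whether the replicates came from separate animals, so agreement between them may be technical.

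The first comparison was of the replicate lists themselves. Sample 1 held 25592 regions that covered 2820.57 kb, and sample 2 held 42619 regions that covered 4810.60 kb. The sample 2 list was 1.67 times as long. The median region was 83 bp wide in sample 1, with an interquartile range of 74 to 141 bp, and 105 bp wide in sample 2, with an interquartile range of 65 to 142 bp. The lowest score in the list was 70.03 in sample 1 and 50.00 in sample 2, and both lists reached the same highest score of 3100. Of the sample 2 regions, 15667 scored below the lowest sample 1 score, a count that assumes the same score scale in both lists. Both lists had a sharp population of narrow regions and a broader population of wider ones. With the boundary at 105 bp in sample 1 and 100 bp in sample 2, narrow regions made up 62.7% of sample 1 and 47.5% of sample 2. The modal width of the narrow regions was 72 bp in sample 1 and 58 bp in sample 2. The narrow regions scored higher than the wide ones within each list, with median scores of 193.9 and 110.4 in sample 1 and of 97.5 and 69.0 in sample 2. Widths within 10 bp of the narrowest region accounted for 37.5% of sample 1 and 20.7% of sample 2.

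**Figure D1:**
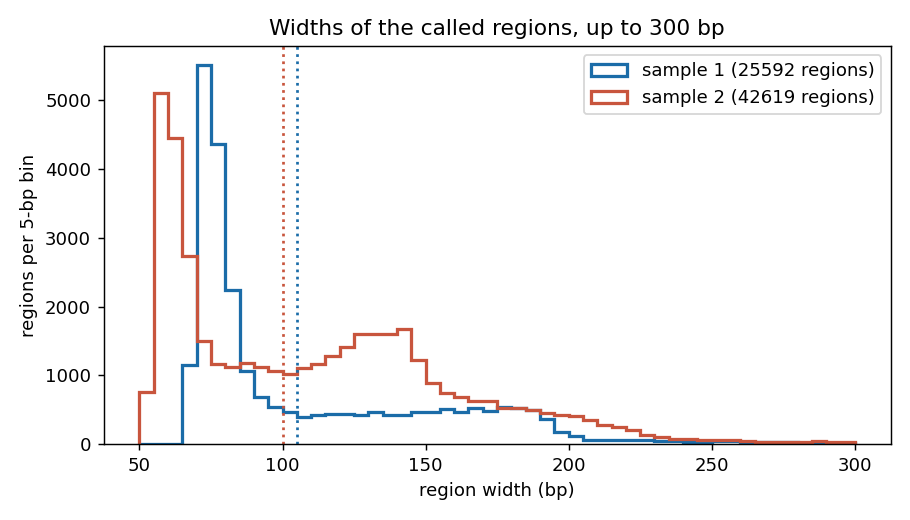
Histogram of region widths in bp (horizontal axis) against the number of regions per 5-bp bin (vertical axis) for sample 1 and sample 2, with dotted lines at the boundaries of 105 bp and 100 bp between narrow and wide regions. The narrow population peaked at 72 bp in sample 1 and at 58 bp in sample 2.

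The second comparison asked which regions were found in both replicates. Of the sample 1 regions, 20582 (80.4%, exact 95% interval 79.9 to 80.9%) overlapped a sample 2 region by at least 1 bp. Of the sample 2 regions, 20643 (48.4%, exact 95% interval 48.0 to 48.9%) overlapped a sample 1 region. Merged, these gave 20574 shared regions with a median width of 131 bp, while 5010 regions were in the sample 1 list only and 21976 in the sample 2 list only. Random placement of the sample 2 regions along the same chromosomes gave a mean of 95.9 ± 9.54 overlaps (SD over 100 placements, highest 117). The observed overlap was 214.7 times the mean of these placements, which did not avoid assembly gaps. None of the placements reached the observed count, and the smallest p that 100 placements can give is 0.0099. Moving every sample 2 region by 5 kb in either direction, which keeps the regional density of each list, left a mean of 160 overlaps. The observed overlap was 128.6 times that mean. A shift of 1 kb left a mean of 207 overlaps and a shift of 50 kb a mean of 137. The observed overlap was 99.4 and 150.2 times these means, so the ratio was lower at the shorter shift. The share of regions found in both lists followed the score. It was 62.97% in the lowest and 91.4% in the highest score decile of sample 1, and 20.7% and 85.0% in those of sample 2. The rise was not uniform over the intermediate deciles, since deciles 4 and 5 of sample 1 (79.8% and 77.9%) lay below decile 3 (81.4%). When sample 2 was reduced to its 25592 highest-scoring regions, 59.1% of the sample 1 regions overlapped one of them.

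**Figure D2:**
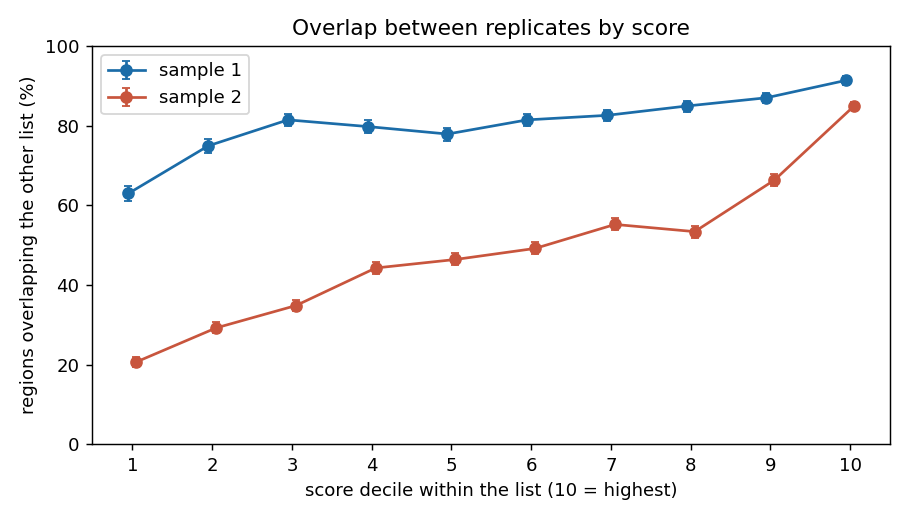
Share of regions that overlapped the other replicate's list (vertical axis, percent, with exact 95% intervals) by score decile within each list (horizontal axis, 10 is the highest). The share reached 91.4% in sample 1 and 85.0% in sample 2 in the highest decile.

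The order of the scores agreed only weakly between replicates. Across the 20651 overlapping pairs, Spearman's rho was 0.176 and Pearson's r was 0.307, correlations across regions, which are not independent replicates. The correlation differed by width. For the 4823 pairs that were wide in both lists rho was 0.472, with an approximate 95% interval of 0.449 to 0.495. For the 7509 pairs that were narrow in both lists it was 0.078, with an interval of 0.054 to 0.102. The width class itself was kept in part: 5611 pairs were narrow in sample 1 and wide in sample 2, and 2708 pairs were the reverse.

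The edges of shared regions fell at the same base in 7.81% of starts and 7.56% of ends over all 20651 pairs. In 28.3% of pairs, a start or an end lay at the same base or 16 bp further in. The distance of 16 bp was read from these data, as the second peak of start offsets in pairs narrow in both lists. No chance value was computed for the share of 28.3%. In pairs narrow in 1 list only, the same base held 5.25% of starts and 5.41% of ends. Among the pairs narrow in both lists, 11.3% started at the same base and 11.7% started 16 bp further in in sample 2. Starts 1 base further in than these positions made up 3.21% and 2.86%. The end edges followed the same course, with 10.8% at the same base and 12.2% at 16 bp further in. Over both edges, the same base was 3.05 times as frequent as 1 base further in (exact 95% interval 2.76 to 3.36). On the outward side the edges fell off gradually, with 8.75%, 6.81% and 4.62% of the starts 1, 2 and 3 bases further out in sample 2, and the same base was 1.32 times as frequent as 1 base further out (1.22 to 1.42). For the pairs wide in both lists the ratios were 4.09 (3.42 to 4.91) inward and 2.05 (1.78 to 2.35) outward. The intervals of these ratios count the start and the end of a pair as independent, which they are not, so they may be too narrow.

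**Figure D3:**
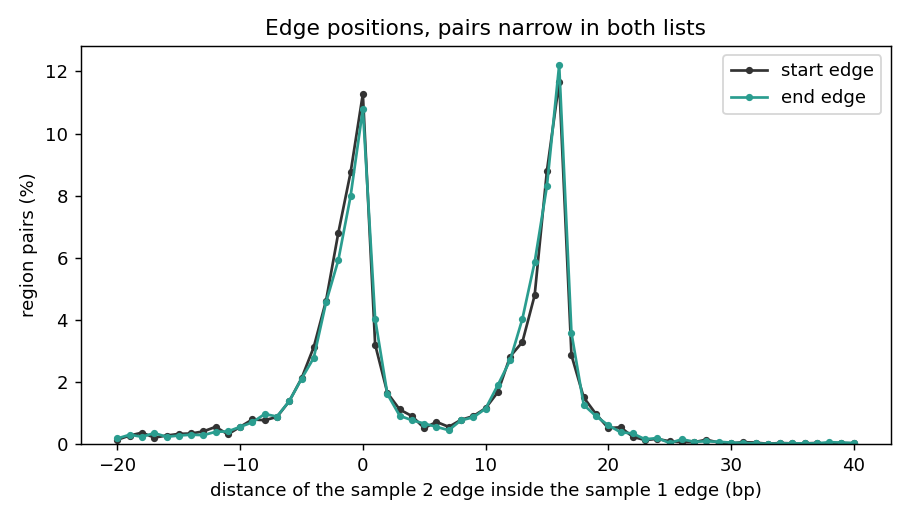
Distance in bp by which the sample 2 edge lay inside the sample 1 edge (horizontal axis, negative where it lay outside) against the percentage of the 7509 pairs narrow in both lists (vertical axis), for start and end edges. Both curves peak at 0 and at 16 bp and drop within 1 bp on the inward side, from 11.3% to 3.21% for start edges at 0, and fade gradually on the outward side.

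The strongest shared regions were chosen by the mean of their score percentiles in the lists. The first was a 3865 bp region on chromosome 17, from 39979868 to 39983732, with a score of 3045.58 in sample 1 and the highest score of 3100 in sample 2. The second lay on chromosome 11 from 108872943 to 108873394, with scores of 2297.98 and 1185.29 in samples 1 and 2. The third lay again on chromosome 17, from 36368152 to 36368602, with scores of 1535.99 and 1396.14. A further chromosome 17 region, from 85636518 to 85636916, scored 923.61 and 665.90. The fifth was a 1820 bp region on chromosome 4, from 3016594 to 3018413, the first region of that chromosome in both lists, with scores of 914.33 and 510.17. On chromosome 3, the region from 5860616 to 5860869 scored 941.50 and 460.12, and the region from 75876289 to 75876544 scored 774.54 and 386.88. The remaining regions among the first 10 lay on chromosome 12 from 25800715 to 25800981, on chromosome 5 from 147072489 to 147072961 and on chromosome 2 from 104142068 to 104142296. Their sample 2 scores were 604.89, 483.98 and 650.81. Whether these regions lie in repeated sequence, such as satellite or ribosomal DNA, where reads from many copies can pile up, was not tested, so their scores cannot be read as occupancy. Their gene content was not analysed here, because the only gene table at hand uses another genome build than the lists.

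Some of the highest-scoring regions were in a single list. Among the 100 highest-scoring regions of sample 1, 7 had no overlap in sample 2. Among the 100 highest-scoring regions of sample 2, 1 had no overlap in sample 1. The highest-scoring sample 1 region without a partner lay on chromosome X from 139917505 to 139917663, with a score of 1305.34 and a distance of 43278 bp to the nearest sample 2 region. The next lay on chromosome 12 from 3109835 to 3110162, with a score of 1242.64. The sample 2 region without a partner lay on chromosome 17 from 39984623 to 39985843, with a score of 1812.07. It was 898 bp away from the nearest sample 1 region, which belongs to the strongest shared region.

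The distribution along the genome was described for the 20550 shared regions on chromosomes 1 to 19 and X, against each chromosome's share of the length spanned by the lists. Chromosome 11 had the highest density, with 1275 shared regions, 10.7 per Mb, a share 1.34 times that of its length (exact 95% interval 1.27 to 1.42). It was followed by chromosome 5 at 10.0 per Mb (1.26 times, 1.20 to 1.32), chromosome 19 at 9.94 per Mb (1.25 times, 1.15 to 1.35) and chromosome 17 at 9.78 per Mb (1.23 times, 1.15 to 1.31). Chromosome 14 had the lowest density among the autosomes, 6.65 per Mb, a share 0.833 times that of its length (0.778 to 0.891). Chromosome X had 591 shared regions, 3.66 per Mb, a share 0.459 times that of its length (0.423 to 0.497). The interval lay above 1 for 9 chromosomes and below 1 for 7. The expected shares include X, whose low count raises the value of every autosome, so these counts depend in part on X. These intervals assume independent regions. Over autosomal windows of 1 Mb, the variance of the count of shared regions was 4.16 times its mean. The intervals are therefore too narrow, and wider ones could reach 1 for some of these chromosomes. Either list alone gave a like value for X, 0.455 times in sample 1 and 0.471 times in sample 2. A further 23 shared regions lay on chromosome Y and 1 on the mitochondrial genome.

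Across the 19 autosomes, the density of shared regions went with the number of protein-coding genes per Mb, counted per chromosome in the GRCm38 gene table. Pearson's r was 0.607 (permutation p = 0.0055, adjusted p = 0.0083) and Spearman's rho 0.660 (permutation p = 0.0031, adjusted p = 0.0046), two-sided. The adjustment covered 3 relations, of the shared regions and of either list alone, for which r was 0.618 in sample 1 and 0.522 in sample 2. Without chromosomes 7 and 11, the chromosomes farthest from the median gene density, r was 0.699.

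**Figure D4:**
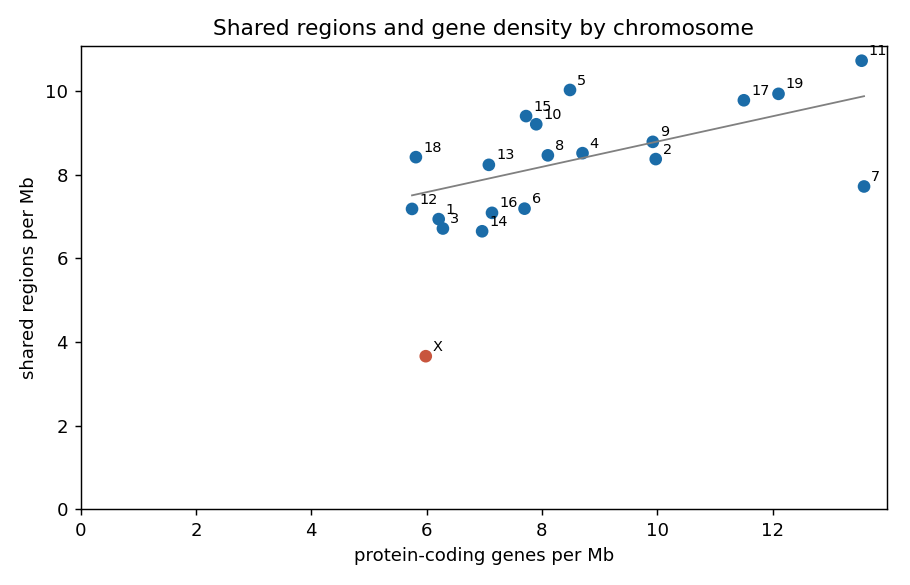
Shared regions per Mb of spanned length (vertical axis) against protein-coding genes per Mb (horizontal axis) for chromosomes 1 to 19 (blue) and X (red), with the least-squares line through the 19 autosomes. Chromosome 11 had the highest density, 10.7 per Mb, and X the lowest, 3.66 per Mb.

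Shared regions clustered within chromosomes. Of the windows of 100 kb, 281 held at least 5 shared regions, against a mean of 44.6 and a maximum of 64 in 100 random placements. The densest window lay on chromosome 2 from 165700001 to 165800000 and held 11 shared regions, while the highest count in any placement was 9. The windows on chromosome 18 from 69500001 to 69600000, on chromosome 4 from 139300001 to 139400000 and on chromosome 5 from 119500001 to 119600000 held 9 each. The rank of the fifth window was tied among 6 windows with 8 shared regions, of which 3 lay on chromosome 5. In windows of 1 Mb, the highest count was 42, on chromosome 11 from 117000001 to 118000000, against a median of 7 over the 2425 autosomal windows, of which 62 held none.

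Regions of at least 1 kb were rare, 12 in sample 1 and 11 in sample 2. Of these, 5 in each list lay on chromosome Y, and 3 in sample 1 and 1 in sample 2 on the mitochondrial genome. On the mitochondrial genome sample 1 had 5 regions that covered 6706 bp, and sample 2 had 1 region, from 5 to 1712, that covered 1708 bp. The mitochondrial region from 4 to 1649 in sample 1 overlapped it.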

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

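The overlap between replicates depended on which sample 2 regions were admitted, and the low density of X kept its direction with a stricter score limit, with either list alone, with reciprocal overlap and against gene content, the alternatives run for it. With only the upper 50% of each list by score, 7447 sample 1 regions were shared (58.1% of those kept), rho was 0.122 and the share on X was 0.613 times its share of length. This limit narrows the range of both scores, which can itself lower rho. Pearson's r was 0.349 there, against 0.307 over all pairs. With a reciprocal overlap of at least 50% of each region, 62.7% of the sample 1 regions were shared (16043 regions) and rho was 0.221. Against the share of protein-coding genes in place of length, X held 0.644 times its expected share. The following alternatives were chosen after seeing the data. With sample 2 limited to scores at or above the lowest sample 1 score, 61.4% of sample 1 regions were shared. With as many top-scoring sample 2 regions as sample 1 has, it was 59.1%. Between wide regions alone 4793 of the wide sample 1 regions were shared (50.3%, rho 0.472), and between narrow regions alone 7509 of the narrow ones (46.8%, rho 0.078). These counts fell in part by construction, since each uses fewer regions. Counting regions with midpoints within 200 bp as shared changed the shared count by less than its interval, to 20601. At these widths that rule is looser than overlap for most regions, so it could hardly lower the count and tests little. The limit of 5 kb on width removed no region and tests nothing. The alternatives meant for gene location, promoter regions, gene lists and motifs were not run, because these results were not computed. Depth is unknown for both lists, so whether a region in 1 list only was absent or missed in the other cannot be said.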

Other observations

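Outside the shared set, the unshared regions were not spread evenly. The 4986 sample 1 regions and the 21919 sample 2 regions on chromosomes 1 to 19 and X without a partner lay at a median of 30.4 kb and 36.2 kb from the nearest shared region. Random placement gave medians of 51.3 kb and 51.8 kb. Over the 2425 autosomal windows of 1 Mb, the count of shared regions correlated with the count of sample 2-only regions (Spearman's rho 0.516) and of sample 1-only regions (0.575), correlations across windows, which are not independent. Leaving out chromosome Y and the mitochondrial genome, 7 of the 100 highest-scoring sample 1 regions and 0.821% of the other sample 1 regions lay within 1 Mb of the first region of their chromosome. In sample 2 these were 1 of 100 and 0.709%. Both limits were set after such regions had been noticed, so these values are a description, and the difference between the samples was not tested.

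The tests below of edges, score limits and X copy number were chosen after the result was seen. The test of gene density on X was chosen after the low density of X had been seen and before the predicted value was computed. The first pattern is that a part of the region edges, 7.81% of starts and 7.56% of ends over all 20651 pairs, fell at the same base in the lists. In pairs narrow in both lists, edges at the same base were 3.05 times as frequent as edges 1 base further in (exact 95% interval 2.76 to 3.36). For these pairs, it stays open whether fragments sheared at random around bound sites could give this. No shearing profile was at hand to set a bound. The narrowest widths, 67 bp in sample 1 and 52 bp in sample 2, limit how far an edge can lie inward. This limit acts on the start and the end of a pair together. The 11.7% of starts that lay 16 bp further in therefore do not settle whether it accounts for the drop at 1 base. The distance of 16 bp is close to the difference between these narrowest widths, and a link between them was not tested. In pairs wide in both lists the ratios were 4.09 (3.42 to 4.91) inward and 2.05 (1.78 to 2.35) outward. If region edges follow fragment ends, random shearing would leave neighbouring bases about equally frequent. Under that assumption, these values argue against it as the only source in wide pairs. How the peak caller set the edges is not given in the sources used here, so the assumption was not tested. The intervals of these ratios treat the start and the end of a pair as independent. Reads exchanged between the multiplexed libraries, which shared their lanes, could give reads at one base in both lists, and the low rank correlation of scores (0.078) neither excludes nor shows it, because the score is not a read count. Sequence that fixes read positions, such as the limits of uniquely alignable stretches, stays open and was not tested, and the design has no second condition against which a biological explanation could be tested.

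The second pattern is the low density on chromosome X, 0.443 times that of the autosomes. X has few genes, but the line through the 19 autosomes at the gene density of X predicted 7.58 shared regions per Mb, with a 95% prediction interval of 5.33 to 9.83, above the 3.66 observed. Gene density as seen between autosomes is therefore not the whole explanation. A single X chromosome in some of the cells may contribute, since regions on chromosome Y were called in both lists, 44 in sample 1 and 80 in sample 2. Whether these Y regions lie in repeated sequence was not tested. The only value set against this explanation was the low density of X itself, so the outcome was fixed and decides nothing. The sex of the animals is not given in the labels. A call limit turns fewer reads into fewer regions by an unknown factor, so a single X cannot be told apart from a lower occupancy of X. The length of X to which reads align uniquely was not computed, and no input library was analysed here. A smaller alignable part of X therefore stays open as well. The size of the deficit also changed with the score limit. Narrow regions scored higher than wide ones in each list, and the value for X was not computed by width class. Score and width therefore cannot be told apart here. With the stricter score limit, X held 0.613 times its share of length, against 0.459 times (exact 95% interval 0.423 to 0.497) over all shared regions.

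The third pattern is the longer list of sample 2. A candidate explanation, if scores mean the same in both lists, is a lower limit on the score: after regions below the lowest sample 1 score were left out, 26952 sample 2 regions remained, 1.05 times the length of the sample 1 list. The limit alone does not give the same regions, as 61.4% of sample 1 regions then had a partner. Whether scores mean the same in both lists is in doubt. The median score was 167.85 in sample 1 and 82.14 in sample 2, and the highest score decile started at 297.14 and 148.77. A difference in depth stays open, because read totals are not given in the sources used here and a score derived from a p-value would rise with depth.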
